A study of Mus musculus with 8 samples.

How the data were processed

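The series holds 8 mouse libraries, 2 from each of 4 cultured cell types of the C57BL/6 strain: embryonic stem cells (ESC, passage 14), induced pluripotent stem cells (iPSC, passage 22), neural stem cells from fetal brain at embryonic day 12.5 (NSC, passage 16) and testicular Sertoli cells (SC, passage 2). Per the labels' protocols, mRNA was purified from total RNA and broken into fragments of about 100 nt. 1 library of each cell type was sequenced as such (RNA-seq), and the other after enrichment of fragments with an antibody against N6-methyladenosine (m6A-seq).

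The deposited table gives 1 line per RefSeq transcript, 19776 in all. Its expression values are FPKM per the file headers, and were made by the authors from the RNA-seq libraries. The submitters' processing notes name CASAVA, TopHat2 2.0.4, Cufflinks 2.0.2 and the mouse build mm9, without saying which did what. The m6A values are yes/no calls (1 modified, 0 not) for 5 regions of each transcript, per the file headers: TcSS, 5' UTR, CDS, TsTS and 3' UTR. The headers do not spell out TcSS and TsTS, so these names are kept as they stand; TsTS is the column between CDS and 3' UTR. The peak caller, its threshold and the control used for it are not given in the sources used here. A call carries no height, so the degree of methylation was not analysed here. Of the transcripts, 18578 are coding (NM) and 1198 non-coding (NR), and the non-coding ones carry 0 calls in any cell type.

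Transcripts were given gene symbols through their RefSeq accessions, with a RefSeq gene table of assembly GRCm38.p6 (19446 transcripts) and GENCODE M21 (104 more); 226 had no match and were left out. Accessions with a numbered suffix (121) were matched by their base. This left 15359 genes, 2827 of them with several transcripts. A gene is represented by its transcript with the highest mean FPKM over the 4 RNA libraries. Because the annotation used for names is of another build than mm9, no coordinates are given. Transcript length and GC content, used in the closing section, came from GENCODE M21 and covered 98.8% of genes.

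Expression was compared as log2(FPKM + 1), which understates the change of genes at low levels, among genes at 1 FPKM or more in at least 1 library compared. A gene counted as different at 2-fold or more. In the comparison of the pluripotent pair (ESC and iPSC) with the differentiated pair (NSC and SC), both libraries of one side had to lie at least 2-fold above both of the other; the same count was made for the other 2 ways of pairing the 4 libraries. A gene counted as m6A-called where any of its 5 regions was called. Calls were compared over genes at 1 FPKM or more in every RNA library compared, so that loss of the transcript was not read as loss of the mark, and overlaps were set against the number that independent lists would share.

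Each cell type has 1 library per assay, so no difference in the results has a replicate check, and no p-values were computed; ESC and iPSC are different cells and not replicates of each other. Shares carry exact (Clopper-Pearson) 95% binomial intervals, which cover counting error over genes only. Gene lists, 23 in number, are described by the median log2 difference of their members and its percentile among 10000 random lists of the same size, drawn with replacement and matched on mean expression in 20 bins; a percentile describes these libraries and is no test. Named genes were taken by fixed rules: the 10 highest and 10 lowest of each RNA comparison at 10 FPKM or more on the higher side, the 10 most highly expressed genes called on one side and not the other of each m6A comparison, all reprogramming factors and m6A enzymes and binders, up to 4 members of each other list with the greatest differences, and the usual identity markers. Unnamed symbols (RIKEN, Gm, LOC and the like) and Y-linked genes were left out of the named genes. The groups, rules, lists and alternatives were fixed before the data were examined, except where the text says otherwise.

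Read depth is unknown for all 8 libraries. The low FPKM values of genes with a single transcript showed no common step between libraries (no ratio bin of 0.02 log2 held more than 1.89% of such genes), so read counts could not be recovered and no detection floor is given. The summed FPKM was 580765 in ESC, 394600 in iPSC, 516215 in NSC and 818860 in SC, so the columns are not on one total. A value of exactly 0 can be a failed estimate or an assignment of all reads to another transcript of the gene: the ribosomal protein gene Rps27 was listed at 0 FPKM in SC and between 69.7 and 339 elsewhere. Genes are therefore said to be listed at 0, and no fold of a single gene is given against such a library; counts and list medians on the log2(FPKM + 1) scale still include these genes, and the counts were also made without them.

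Planned pseudocounts and centring for graded m6A levels did not apply, since the calls are yes/no. Alternatives covered the pseudocount (0.1 and 5), the expression filter (none, and 5 FPKM), a 4-fold threshold, scaling of the libraries by their median ratio to the geometric mean over genes at 1 FPKM or more in all 4, every transcript as its own item, sums over a gene's transcripts, calls required in 2 or more regions, calls from any transcript of a gene, the omission of each cell type in turn, and 5 bins for the random lists. A further choice for the RNA comparisons, leaving out genes listed at 0, and 1 for the m6A extent, counting coding transcripts alone, were added after seeing the data, as were random lists matched on transcript length or on GC content in place of expression. For the comparison of m6A calls with expression, the rule set beforehand put genes called in 1 of 2 cell types against genes called in both; the direct contrast between the genes called in the first alone and those called in the second alone was added later. Computation used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

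The rules were tested on simulated libraries made from the ESC values with a noise of 0.1 log2 and 200 changed genes at 10 FPKM or more. Of genes changed by 4-fold, 200 of 200 were recovered in the comparison of the pairs (10575 genes), in ESC against iPSC (10498) and in NSC against SC (10505), with 0 other genes called. Every simulated library was a copy of ESC, and this noise is too small to carry an unchanged gene past 2-fold. The 0 other calls were thus fixed by the setting and tell nothing about false calls in the real libraries. There, 26.5% of genes lay beyond 2-fold between ESC and iPSC. Of genes changed by exactly 2-fold, 22 of 200 were recovered in the comparison of the pairs, 87 of 200 in ESC against iPSC and 90 of 200 in NSC against SC. A change of 2-fold thus lies on the threshold and is mostly missed, above all by the pair rule, so the counts leave out many genes near 2-fold. Independent simulated calls over 8259 genes gave 842 genes called on 1 side only for the pluripotent against the differentiated pair, 811 for ESC with NSC and 849 for ESC with SC. These calls were drawn at the same rate in every cell type, while the real shares ran from 58.0% in NSC to 69.2% in iPSC. They therefore give no baseline for an imbalance between the sides of a pairing. Of 500 random lists of 20 unshifted genes, each set against 400 random lists, 25 fell outside the central 95% of percentiles.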

Results

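Expression and m6A calls were compared in 4 mouse cell types: ESC, iPSC, NSC and SC. N6-methyladenosine (m6A) is a methyl mark on adenosines inside mRNA. The design sets 2 pluripotent cell types (ESC and iPSC) beside 2 differentiated ones (NSC and SC), and within each pair asks how alike the members are. Every cell type had 1 RNA library and 1 m6A library, so no difference given here has a replicate check. The table held 15359 genes, of which 13577 reached 1 FPKM in at least 1 library and 8259 in all 4. Genes at 1 FPKM or more numbered 10415 in ESC, 10556 in iPSC, 10986 in NSC and 11341 in SC. Read depth is unknown; the 10 most abundant genes took 11.1% of the summed gene values in ESC, 8.37% in iPSC, 9.83% in NSC and 10.1% in SC. Genes listed at exactly 0 numbered 344 in ESC, 191 in iPSC, 1126 in NSC and 694 in SC.

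Marker genes separated the libraries. Pou5f1 (NM_013633), the transcription factor OCT4 of pluripotent cells, stood at 602 FPKM in ESC and 554 in iPSC, was listed at 0 in NSC and stood at 0.0761 in SC; summed over transcripts it stood at 1051 in ESC and 556 in iPSC. Nanog (NM_028016) followed the same order with 254, 232, 0.0296 and 0.137 FPKM in ESC, iPSC, NSC and SC, and Zfp42, also called Rex1, stood at 28.8 and 33.0 in the pluripotent libraries. The Sertoli cell regulators Sox9 and Wt1 reached 106 and 105 FPKM in SC, and Amh, the anti-Müllerian hormone gene, 3.32. The NSC library carried neural stem cell markers at low levels. Pax6 stood at 7.46 FPKM there (15.4 summed over transcripts) against 0.0529 in SC, while Nes, the nestin gene, stood at 9.10 in NSC and 85.9 in SC, and Fabp7 at 0.380 and 4.73. The median over 22 neural stem cell markers was 4.71 FPKM in NSC and 1.04 in SC, and that over 21 Sertoli cell markers was 75.7 in SC and 0.0377 in NSC. The SC library also held fibroblast and peritubular myoid markers at a median of 15.5 FPKM, against 0.328 in NSC, 2.09 in iPSC and 0.102 in ESC.

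**Figure D1:**
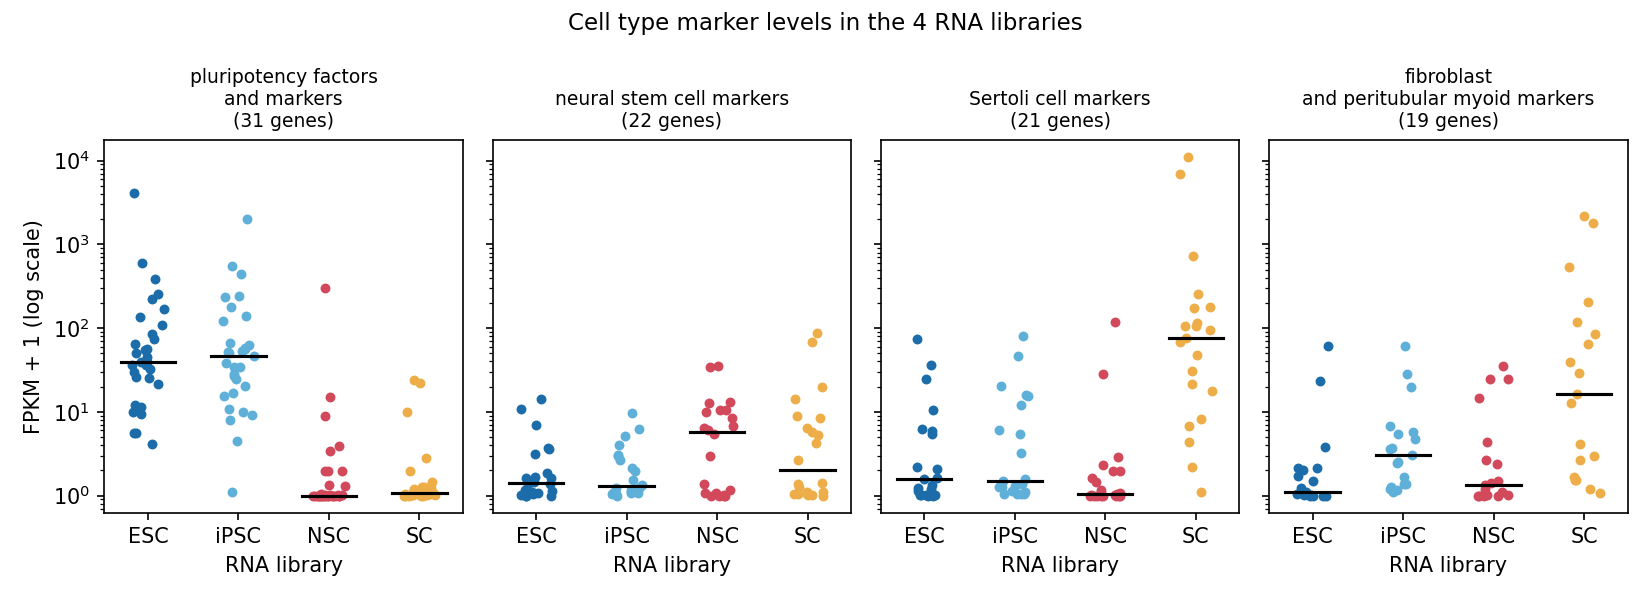
Each point is a gene of 1 marker list, placed by its FPKM + 1 on a log axis in each of the 4 RNA libraries, and each black bar is the list's median. The pluripotency list has medians of 38.2 and 45.4 FPKM in ESC and iPSC, and the Sertoli cell list a median of 75.7 FPKM in SC.

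The comparison of pluripotent with differentiated cells was led by known pluripotency genes. Dppa5a (NM_025274) reached 4078 FPKM in ESC and 1986 in iPSC, against 0.227 in SC, and was listed at 0 in NSC. Tdgf1, which encodes the Nodal co-receptor Cripto, stood at 381 and 439, Fbxo15 at 167 and 139, and Utf1 at 108 and 241, all under 1 FPKM in both differentiated libraries. Wfdc2, Tex19.1 and Zscan4f were also among the 10 genes with the widest gap, as was Ash2l, whose listed transcript was at 0 in NSC and SC but whose summed values were 78.0, 127, 31.8 and 39.3. In the other direction stood Tmem176b (NM_001164208; 0.210, 0.981, 178 and 399 FPKM in ESC, iPSC, NSC and SC), Tmem176a, the matrix proteoglycan gene Prelp, Emp3, Mxra8, Pik3ip1 and Mgst1. Ccnd2, encoding cyclin D2, stood at 0.254, 0.597, 39.2 and 229.9 FPKM, Cdh2, encoding N-cadherin, at 0.223, 0.661, 37.5 and 157, and Anxa2, encoding annexin A2, at 433 in NSC and 1318 in SC, above 8.18 in ESC.

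In total 679 of 13577 genes lay at least 2-fold higher in both pluripotent libraries than in both differentiated ones, and 1696 lay at least 2-fold lower. Without genes listed at 0 these were 408 and 1670, and the pluripotent-high count was 1081 with pseudocount 0.1 and 281 with pseudocount 5, against 716 differentiated-high genes with pseudocount 5. The other pairings gave 76 and 91 genes (ESC with NSC against iPSC with SC) and 261 and 110 (ESC with SC against iPSC with NSC). The balance between higher and lower genes depended on the scaling of the libraries: pluripotent-high genes made up 28.6% of the total as deposited and 56.3% (1145 against 888 genes) after scaling by the median ratio, which moved the median log2 difference of all genes from -0.64 to -0.12. Without ESC, iPSC, NSC or SC the pluripotent-high count was 969, 1228, 1146 or 1252 and the differentiated-high count 2384, 2982, 4949 or 2928. Fewer libraries then have to meet the rule, which raises the counts but does not account for their spread. The count of 4949 rests on SC alone on the differentiated side, whose median ratio lay at 0.63 log2, against 0.06 in NSC.

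Several gene groups parted along the same lines. Of 31 pluripotency genes, 28 were at least 2-fold higher in both pluripotent libraries and 0 lower, with a median log2 difference of 4.54 above every random list (percentile 100). Two-cell-stage-like genes, which mark a rare state of ESC cultures, were higher in 5 of 8 measured, with a median of 3.77 (percentile 100) that rests on genes listed at 0 in NSC and SC, such as Zscan4c and Tcstv1 at 40.9 and 20.3 FPKM in ESC. Germ cell and Leydig cell markers were higher in 5 of 9 (1.82, percentile 99.98), led by Stra8 and Mael at 35.8 and 6.91 FPKM in ESC. Of 4 blood, endothelial and macrophage markers 2 were higher, Pecam1 and Cd74 (1.74, percentile 99.3). Cyclins and replication genes had a median of 0.83 and Polycomb and DNA methylation genes of 0.73, both at percentile 100, with 4 of 26 and 4 of 17 members higher, among them Ccne1, Mcm5, Dnmt3l and Dnmt3b, and 2 of each list lower, among them Ccnd2 and Tet3. Tet3 stood at 0.297, 0.477, 17.6 and 7.58 FPKM in ESC, iPSC, NSC and SC. In the same order the median FPKM of the Polycomb and DNA methylation list was 7.52, 17.5, 15.5 and 6.07. As a whole this list thus did not part the pairs, with NSC above ESC. That of cyclins and replication genes was 57.8, 61.2, 39.2 and 22.3, lowest in SC.

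Lists that lay lower in the pluripotent libraries held structural and signalling genes. Collagen genes had a median log2 difference of -2.17 (percentile 0), with 6 of 26 at least 2-fold lower in both pluripotent libraries and 1 higher; Col5a2 stood at 0.0655, 1.47, 23.9 and 206 FPKM in ESC, iPSC, NSC and SC. The fibroblast and peritubular myoid list had a median of -2.24 and the Sertoli cell list of -2.40, both at percentile 0, although only 3 of 16 and 1 of 21 members passed in both differentiated libraries, since most were high in SC alone, and 1 Sertoli cell marker, Nr0b1, was higher in both pluripotent libraries. Genes of Notch, Wnt, TGF-beta and BMP signalling were lower in 7 of 25 (-1.70, percentile 0.03), Tgfb3 and Tgfb2 among them, while Nodal was higher, at 42.9 and 44.9 FPKM in ESC and iPSC. Neural stem cell markers had a median of -1.39 (percentile 0.3, but 17.6 among genes at 5 FPKM or more), with 3 of 20 lower and 2 higher, the latter Olig1 and Olig2. The neuron, astrocyte and oligodendrocyte list had a median of -1.66 (percentile 1.09, but 5.13 with random lists matched on transcript length), with 1 of 6 lower, and X-inactivation and Y-linked genes of -2.25 (percentile 0.735, but 2.74 at 5 FPKM or more), with 3 of 5 lower. Other lists did not lie lower than random lists. Ribosomal protein genes (0.05, percentile 97.1) and Hox genes (0.51, percentile 93.8) had 4 of 80 and 1 of 10 members higher and 0 lower. After scaling their medians were 0.73 and 0.96. With random lists matched on length their percentiles were 77.4 and 97.9, and with GC content 100 and 98.7. Zfp genes had 17 of 318 higher and 35 lower. Their median of -0.56 lay above most random lists (percentile 98.2), as the median of all genes was -0.64. This percentile was 90.8 with pseudocount 0.1, 94.3 after scaling and 88.2 with random lists matched on GC content. After scaling, the medians turned from negative to positive for germ layer regulators (-0.47 to 0.52), housekeeping genes (-0.40 to 0.26), imprinted genes (-0.40 to 0.01) and oxidative phosphorylation genes (-0.05 to 0.62), so that no direction is given for these.

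ESC and iPSC were the most similar pair, with a Pearson correlation of 0.884 across 11425 genes on the log2 scale, against 0.615 to 0.696 for the other 5 pairs. The difference ESC minus iPSC was lower for long transcripts (Spearman's rho -0.44 across 11338 genes) and higher for transcripts rich in GC (0.48). The pluripotent minus the differentiated pair also had a trend with length (-0.28, and 0.04 for GC), and NSC minus SC had 0.11 (-0.15 for GC). After the trends were seen, lists were also set against random lists matched on length or GC content. Cytosolic ribosomal protein and oxidative phosphorylation genes lay higher in ESC; with length-matched lists their percentiles were 99.8 and 99.1. Of 80 cytosolic ribosomal protein genes, 35 were at least 2-fold higher in ESC and 1 in iPSC (median log2 difference 0.94, percentile 100), among them Rpl23 at 1850.3 and 636 FPKM and Rpl36a at 3049.9 and 1073. Of 75 oxidative phosphorylation genes, 27 were higher in ESC and 0 in iPSC (0.88, percentile 99.99), with Cox6b1 at 882 and 204. The homeobox gene Cdx1 stood at 82.7 FPKM in ESC and 2.71 in iPSC, and 4 of 7 Hox genes were higher in ESC (1.17, percentile 99.93), all at low levels and each under 2-fold with pseudocount 5. Ppp1r14d, Bglap3, Tnni3 and Ly6e were also among the widest differences.

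Polycomb, fibroblast and imprinted genes lay higher in iPSC. Polycomb and DNA methylation genes had a median of -1.004 (percentile 0), with 8 of 16 higher in iPSC and 2 in ESC; Dnmt3l stood at 38.0 FPKM in ESC and 177 in iPSC, Rnf2 at 7.52 and 32.0, and Tet1 at 3.09 and 14.4. Collagen genes had a median of -0.88 (percentile 0.47), but the percentile was 6.92 with pseudocount 0.1, 19.6 at 5 FPKM or more, 3.27 after scaling and 5.16 with length-matched lists. Fibroblast and peritubular myoid markers were higher in iPSC in 8 of 13 and in ESC in 1 (-1.21, percentile 0), with Acta2 at 0.247 and 18.8 and Tagln at 1.12 and 27.7. Imprinted genes were higher in iPSC in 7 of 17 and in ESC in 2 (-0.66, percentile 1.52), with Peg10 at 1.83 and 25.6 FPKM, Mest at 3.17 and 27.9 and Peg3 at 1.25 and 10.6. Zfp genes were higher in iPSC in 46 of 248 and in ESC in 14 (-0.32, percentile 0.03), but their percentile was 51.4 with lists matched on GC content. Car4, Spry4, Aebp2 and Fam169a were among the widest differences; so were several small RNA genes (Snora15, Snora33, Snora2b) that were listed at 0 in ESC. Some listed differences were checked against sums over transcripts. Rpl34, Sall4 and Zfp57 stood higher in ESC in the sums, at 921 and 48.4, 63.7 and 23.4, and 210.2 and 80.1 in ESC and iPSC. For Tmem39a the listed difference came from 1 transcript, as its summed values were 35.0 and 46.2. The differences of Aebp2, Ly6e and Fam169a were narrower in the sums, at 11.1 and 61.5, 71.3 and 17.96, and 3.76 and 29.3. The pluripotency list did not lean to either side (7 of 31 higher in each, median 0.04, percentile 9.22), nor did two-cell-stage-like genes (0 of 8 in each, -0.20, percentile 19.7). In total 1481 genes were at least 2-fold higher in ESC and 1549 in iPSC, or 669 and 498 with pseudocount 5.

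Clu (NM_013492), which encodes the secreted chaperone clusterin and is abundant in Sertoli cells, stood at 11071 FPKM in SC and 0.615 in NSC. The contractile genes Acta2 (1795 and 0.0110) and Tagln (2166 and 0.328), the retinaldehyde dehydrogenase gene Aldh1a1 (1609, listed at 0 in NSC), Gstm2 (10949 and 5.95), Ccn2, Ccl17, Prss35 and Igfbp7 were the other genes far higher in SC; Tpm1 was too, though its summed NSC value was 77.2. NSC was higher for the neurogenic factor genes Neurod1 (125 and 0.0120) and Dll3 (162 and 0.125), for Pla2g2e and Laptm5, and for Tff3 at 1138, listed at 0 in SC. Mir703 and Snora28 were also listed at 0 in SC, as were Rps27 and Hnrnpa1; summed over transcripts Hnrnpa1 stood at 69.6 in SC and Rps27 well below its 361 in NSC.

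By list, 19 of 20 Sertoli cell markers were higher in SC (median log2 difference -5.96, percentile 0), including Inha at 719 FPKM, as were 12 of 15 fibroblast and peritubular myoid markers (-3.05, percentile 0), 17 of 24 collagen genes (-2.96, percentile 0) and 15 of 22 signalling genes (-1.44, percentile 0.25); 1, 2, 3 and 2 members of these lists were higher in NSC. The steroidogenic genes Star and Cyp11a1, used as Leydig cell markers, stood at 56.0 and 46.3 FPKM in SC. Of 18 neural stem cell markers 10 were higher in NSC and 8 in SC (1.18, percentile 99.88), Prom1 among those in NSC and Ttyh1 and Emx2 among those in SC. NSC was also higher for cyclins and replication genes (12 of 26, 0.90, percentile 100), for Polycomb and DNA methylation genes (7 of 14, 0.96, percentile 99.96) and for ribosomal protein genes (31 of 77, 0.85, percentile 100), with 4, 0 and 3 members higher in SC. The cell cycle inhibitor genes Cdkn2b and Cdkn2a went the other way, at 164 and 66.5 FPKM in SC. In total 1870 genes were at least 2-fold higher in NSC and 4424 in SC of 12433, so that NSC-high genes made up 29.7% of the differences; after scaling the counts were 2734 and 2767 (49.7%), and the median of all genes moved from -0.51 to 0.03. With pseudocount 5 the NSC-high count was 894.

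Enzymes and binding proteins of m6A were expressed in all 4 libraries with few exceptions. Mettl3, the catalytic methyltransferase, stood at 9.78 FPKM in ESC, 12.1 in iPSC and 20.7 in SC, with NSC near iPSC, and its partner Mettl14 at 6.48, 10.8, 11.1 and 9.42 in ESC, iPSC, NSC and SC. The demethylase genes Fto (9.69, 11.1, 26.3 and 31.8) and Alkbh5 (9.45, 11.3, 27.6 and 22.7) lay higher in the differentiated libraries as deposited. Fto passed the 2-fold rule and Alkbh5 did not; after scaling the mean difference of Fto also lay under 2-fold. The reader Igf2bp1 stood at 30.1 and 28.1 in ESC and iPSC and 0.485 in SC, and was listed at 0 in NSC; Igf2bp3 stood at 18.1, 7.94, 0.263 and 12.8. The readers Ythdf1, Ythdf2 (not with pseudocount 5) and Ythdf3 were at least 2-fold higher in iPSC than in ESC, at 12.6 and 2.04 FPKM for Ythdf3. As a list the 21 genes had 1 higher member between the pairs, Igf2bp1, and 1 lower, Fto, with a median of -0.45 (percentile 80.4) that became 0.18 after scaling. The 16 microRNA pathway genes had a median of -0.62 (percentile 61.2), 0.07 after scaling; Lin28a was the widest, at 20.5 and 56.8 FPKM in ESC and iPSC.

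NSC carried m6A calls on the smallest share of its expressed genes. Of genes at 1 FPKM or more, 69.0% were called in ESC (95% interval 68.1 to 69.9), 69.2% in iPSC (68.3 to 70.0), 58.0% in NSC (57.1 to 58.9) and 66.7% in SC (65.8 to 67.6). Called genes had 1.957, 2.05, 2.16 and 1.92 called regions on average. TsTS and CDS were the regions called most often: TsTS in 48.5% of genes in ESC, 47.5% in iPSC, 36.8% in NSC and 43.1% in SC, and CDS in 40.8%, 45.2%, 43.6% and 46.1%. The 3' UTR was called in 25.99%, 32.3%, 27.1% and 22.0%, and the 5' UTR in 3.13%, 4.58%, 5.07% and 4.71%. ESC stood apart in TcSS, called in 16.5% of genes against 11.9% in iPSC, 12.48% in NSC and 12.2% in SC. By list, ribosomal protein genes were called seldom, in 26 of 80 genes in ESC (32.5%), 16 of 79 in iPSC (20.3%), 1 of 75 in NSC (1.33%) and 19 of 76 in SC (25.0%). All lay below every random list matched in 20 bins of expression (percentile 0). Such bins may be coarse at the top, where this list lies, with medians of 2010, 1268, 2178 and 1111 FPKM. The span of the highest bin was not tabulated. The percentile therefore does not separate a trait of this list from very high abundance. Collagen genes were called in 22 of 22 in SC (percentile 99.995), signalling genes in 13 of 13 in ESC and 20 of 20 in iPSC (percentiles 99.4 and 99.97, both inside the central 95% at 5 FPKM or more), and pluripotency genes in 28 of 30 in iPSC (percentile 100). Imprinted genes were called in 2 of 14 in NSC (percentile 0.07) and in 9 of 14 in SC (percentile 35.4). The imprinted list names the non-coding genes Meg3, Rian, Mirg and H19, and non-coding transcripts carry 0 calls in these data. The share was not taken over coding members alone, so part of a low share may be fixed in advance.

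**Figure D2:**
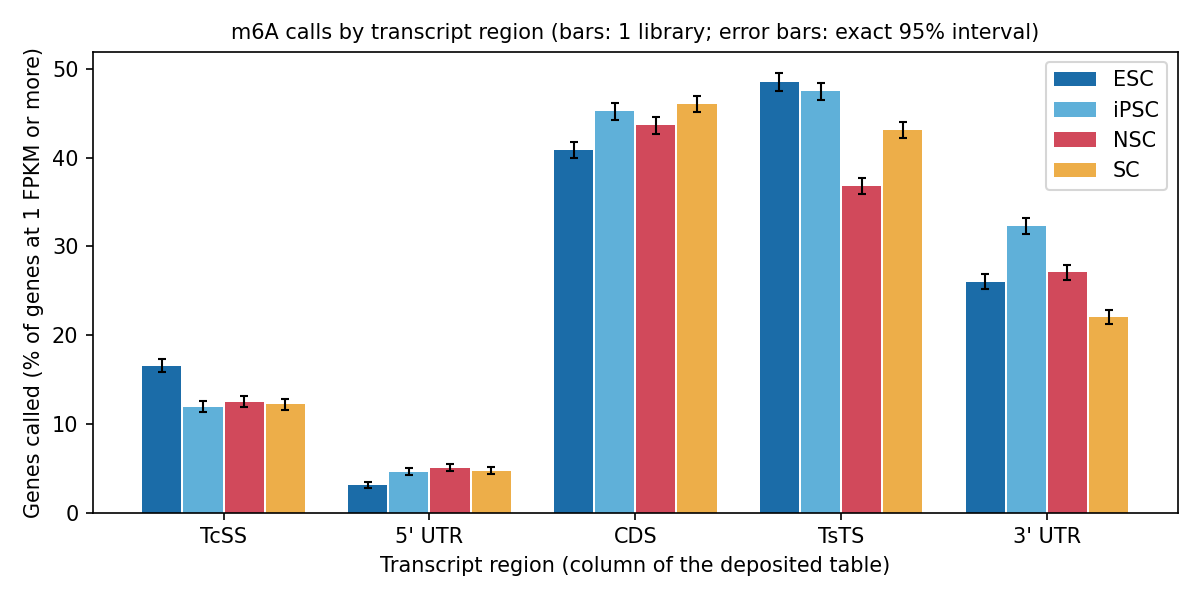
Bars give the percent of genes at 1 FPKM or more that were called in each transcript region, in 1 library per cell type, with exact 95% intervals that cover counting error over genes only. TsTS was called in 48.5% of genes in ESC and 36.8% in NSC.

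The 4 reprogramming factors had a median log2 difference of 2.36 between the pairs (percentile 99.99), but they did not move together. Pou5f1 and Sox2 were at least 2-fold higher in both pluripotent libraries, while Klf4 and Myc passed the rule neither way. As deposited, Myc stood higher in both differentiated libraries, above all in NSC. The order of SC (7.07 FPKM) and iPSC (5.43) depends on the scaling, whose shifts were 0.63 log2 in SC and -0.33 in iPSC. The factors carried calls wherever they were expressed, apart from Myc in NSC. Pou5f1 was called in 2 regions in ESC and in 2 in iPSC. Sox2 was called in 5, 4 and 5 regions in ESC, iPSC and NSC, at 84.6, 119 and 14.3 FPKM, and stood at 0.255 in SC with 0 regions. Klf4 was called in 5, 4, 1 and 4 regions, with FPKM of 136, 62.1, 303 and 21.2. Myc was called in 2, 3, 0 and 3 regions, with FPKM of 0.807, 5.43, 579 and 7.07 and summed values of 2.98, 18.3, 599.5 and 30.9; the library with its highest level, NSC, was the one without a call. Nanog was called in 2 regions in both ESC and iPSC, and Dppa5a, the most abundant of the pluripotency genes, in 0.

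Many genes were called in all 4 cell types, and few in the pluripotent or the differentiated pair alone. Of the 8259 genes expressed in all 4, 3776 (45.7%) were called in all 4 and 1185 (14.3%) in none. Calls in both ESC and iPSC and in neither NSC nor SC were found on 209 genes. The most abundant of these were Rpl41, Mif, which encodes a cytokine, Bsg, the translation factor genes Eif3h and Eif3l, Tuba1c, the proteasome subunit genes Psmb1 and Psmb7, C1qbp and Ppp1cc. The converse held for 63 genes, among them Vdac3, Rpn2, Ddx1, Vps29, Rap1b, the clathrin gene Cltc, Nsmce2, Idi1, Akirin1 and Rab6a. Together 272 genes parted the pluripotent from the differentiated pair; at 5 FPKM or more the 2 counts were 122 and 20, and with no expression filter 662 and 296. ESC with SC against iPSC with NSC parted more, 538 (305 called in ESC and SC, 233 in iPSC and NSC), and the remaining pairing fewer, 160 called in ESC and NSC but neither iPSC nor SC (77) or the reverse (83). At 5 FPKM or more these pairings gave 328 and 88, and with no filter 851 and 310. Without ESC, iPSC, NSC or SC the pluripotent count was 436, 486, 552 or 1101 and the differentiated count 207, 341, 240 or 251, with fewer libraries to meet the rule. The count of 1101 rests on NSC alone on the differentiated side, the library with the smallest share of genes called. How far unequal shares of calls account for the imbalance of 209 against 63 was not tested.

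**Figure D3:**
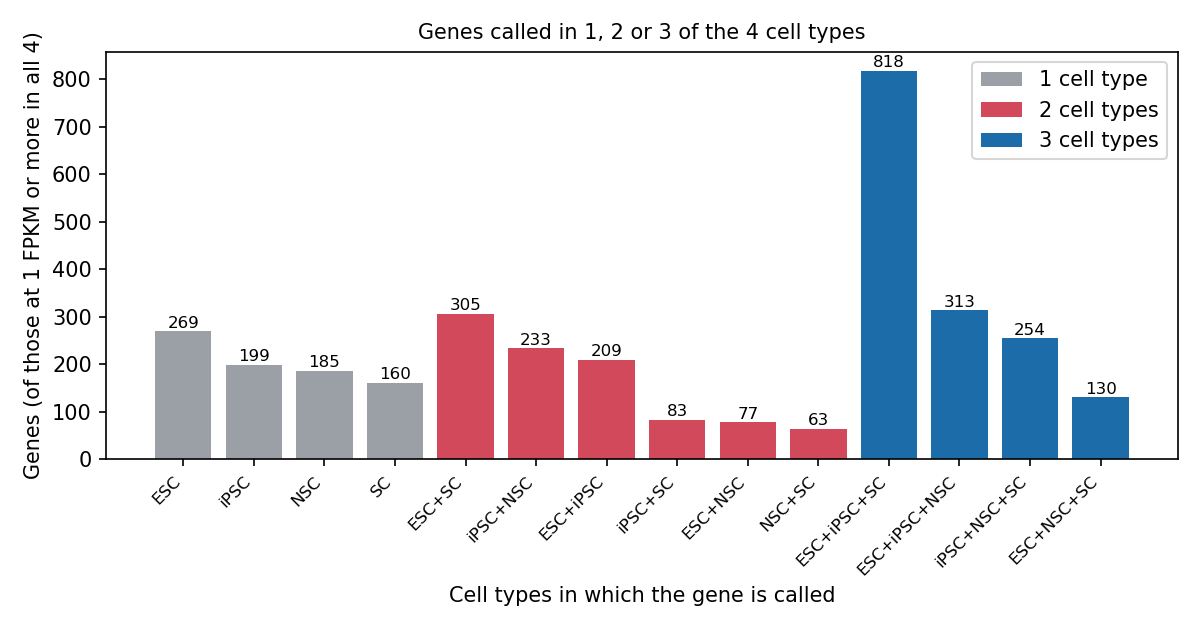
Bars count the genes at 1 FPKM or more in all 4 RNA libraries that were called in 1, 2 or 3 cell types, by combination. Among genes called in exactly 2, ESC with SC has 305, iPSC with NSC 233 and ESC with iPSC 209.

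In each of the 5 regions taken alone, calls overlapped most between ESC and SC and between iPSC and NSC, by a wide margin in TcSS and a narrow one for iPSC and NSC in CDS, TsTS and the 3' UTR; with the regions pooled, only ESC and SC stood apart by phi. The phi coefficient, a correlation for yes/no values, was taken over the 8259 genes. For any region it was 0.595 for ESC and SC, 0.541 for ESC and iPSC, 0.543 for iPSC with either NSC or SC, 0.434 for NSC and SC and 0.386 for ESC and NSC. By the number called in both over that of independent lists, among the genes expressed in each pair, iPSC and NSC (1.28) and ESC and SC (1.27) stood highest, against 1.20 to 1.24 for the other 4 pairs. In TcSS it was 0.496 for iPSC and NSC and 0.395 for ESC and SC, against 0.107 to 0.161 for the other 4 pairs, and in the 5' UTR 0.671 for iPSC and NSC and 0.495 for ESC and SC, against 0.269 to 0.408. For ESC and SC, iPSC and NSC, and the highest other pair it was 0.654, 0.598 and 0.590 in CDS, 0.627, 0.555 and 0.546 in TsTS, and 0.667, 0.621 and 0.604 in the 3' UTR.

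**Figure D4:**
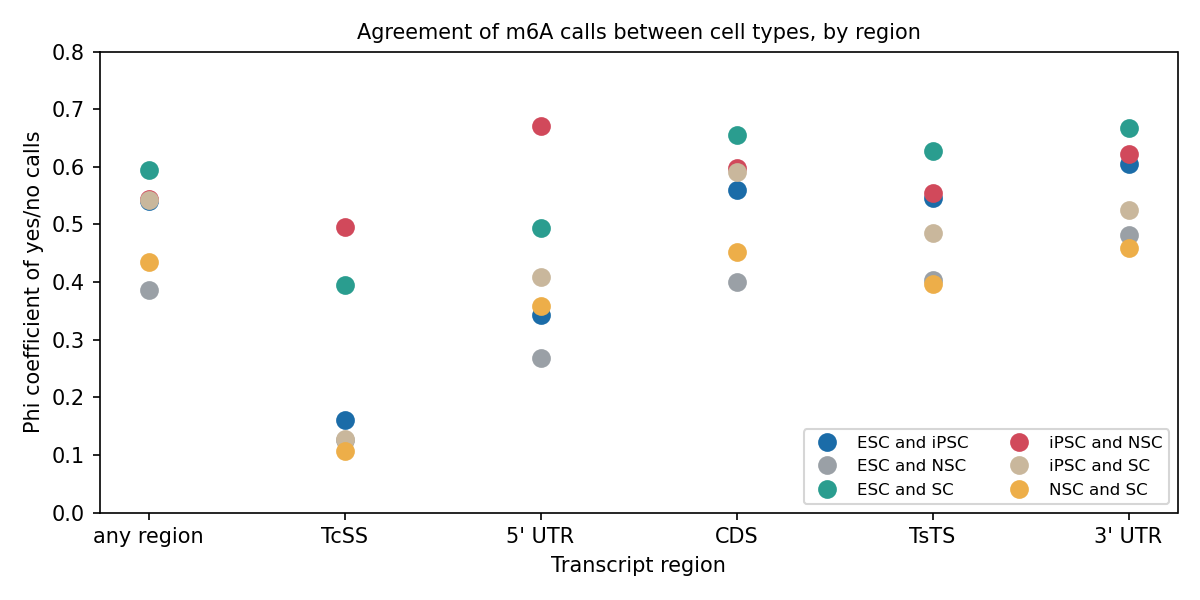
Points give the phi coefficient of yes/no calls across 8259 genes for each pair of cell types, in any region and by region. In TcSS iPSC with NSC (0.496) and ESC with SC (0.395) lie above the other 4 pairs.

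Between ESC and iPSC, of 9546 genes expressed in both, 5742 were called in both, against 4628 for independent lists, 936 in ESC alone and 873 in iPSC alone. With no filter the last 2 were 1506 and 1574, and at 5 FPKM or more iPSC alone had 362. Ranking by abundance brings ribosomal protein genes to the top, and their share among differing calls was not tested. The most abundant called in ESC alone were the ferritin light chain gene Ftl1, the metallothionein gene Mt2 and the ribosomal protein genes Rpl8, Rps18, Rplp0, Rpl36, Rpl28, Rps15, Rpl26 and Rpl11. Those called in iPSC alone were Rpl35, Rps9, Rps10, Rps25, Rps27l and Rpl38, the tubulin gene Tuba1b, the superoxide dismutase gene Sod1 and the respiratory chain genes Cox4i1 and Cox8a.

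Between NSC and SC, of 9894 genes expressed in both, 5053 were called in both, against 4098 for independent lists, 988 in NSC alone and 1658 in SC alone. At 5 FPKM or more NSC alone had 598, and with no filter SC alone had 2491. Eef1a1, which encodes a translation elongation factor, Rps2, Rpl28, Rpl11, Rpl19, Rpl7a, Rpl29 and Rpl4, with Gapdh and Hsp90ab1, were the most abundant called in SC alone. The most abundant called in NSC alone were the ATP synthase genes Atp5b and Atp5a1, the actin gene Actg1, the cofilin gene Cfl1, Mt1, Cox8a, Pebp1, Eif5a, Slc25a5 and the glycolytic gene Pgk1.

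Within each cell type the share of genes called was lowest or second lowest at the lowest expression and fell again at the highest, most of all in iPSC and NSC. In NSC 67.4% of genes in the middle of 5 groups by expression were called and 43.2% in the highest, and in iPSC 75.1% and 59.1%. In SC the shares were 75.3% and 65.4%, and in ESC 72.3% and 71.5%, where the intervals overlap (70.3 to 74.2 and 69.5 to 73.5). In the lowest group they were 56.0% in ESC, 63.7% in iPSC, 52.3% in NSC and 49.7% in SC. Spearman's rho between FPKM and the number of called regions, across genes that are not independent replicates, was 0.16 in ESC, -0.06 in iPSC, -0.09 in NSC and 0.14 in SC. With genes at 5 FPKM or more, rho was -0.00143 in ESC and -0.0247 in SC, so its direction there depends on the filter.

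**Figure D5:**
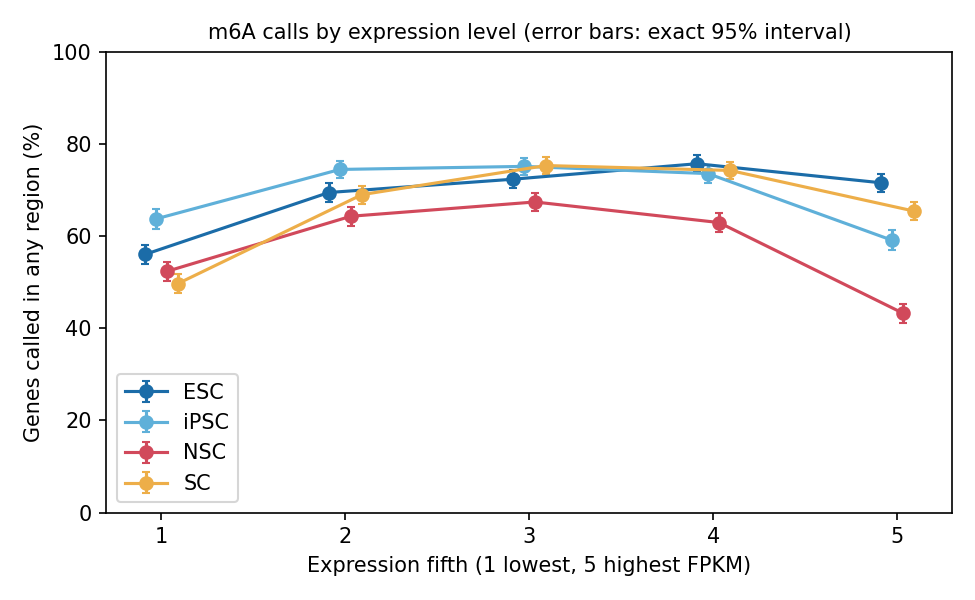
Points give the percent of genes called in any region in 5 groups by FPKM among genes at 1 FPKM or more, in 1 library per cell type, with exact 95% intervals. The highest group stands at 43.2% in NSC and 71.5% in ESC.

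Genes called in 1 of 2 cell types were mostly shifted in expression towards that cell type, relative to genes called in both. Genes called in ESC and not iPSC had a median log2 difference (ESC minus iPSC) 0.43 above that of genes called in both (bootstrap 95% interval over genes 0.39 to 0.50), and genes called in iPSC and not ESC lay at -0.43 from it (-0.49 to -0.36). For ESC and SC the shifts were 0.78 and -0.65, for iPSC and SC 0.68 and -0.36, and for ESC and NSC 0.22 and -0.43. As means within 5 groups of similar expression the shifts were 0.41 and -0.38 for ESC and iPSC, 0.78 and -0.78 for ESC and SC, 0.56 and -0.40 for iPSC and SC, and 0.03 and -0.40 for ESC and NSC. The other pairs did not follow this form. For iPSC and NSC the shifts were -0.09 (-0.18 to -0.01), away from iPSC, and 0.01 (-0.10 to 0.11); with no expression filter the first turned to 0.58. For NSC and SC both groups lay above genes called in both, by 0.36 for genes called in NSC (0.26 to 0.45) and 0.18 for genes called in SC (0.08 to 0.26), the latter away from SC; with no filter that one turned to -0.28. Within groups of similar expression these were -0.13 and -0.04 for iPSC and NSC, and 0.20 and 0.22 for NSC and SC. These shifts carry no direction of cause.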

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

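The tests of cell mixture and of neural differentiation for the NSC library were chosen after its values were seen; the others were set beforehand. The reading of the length and GC tests was altered once after their values were seen, and was then returned to the wording fixed beforehand, which is used here. Each cell type has 1 library per assay, so a biological difference between the cell types stays open for every pattern and was not tested.

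Several named genes stood below both pluripotent libraries in 1 differentiated library and above them in the other; the difference was not tested. The log2 difference (NSC minus SC) was -10.60 for Ccn2, -12.74 for Clu, -4.88 for Id3, -10.03 for Igfbp7, 3.77 for Klf4, 4.99 for Rpl22l1 and -10.72 for Tpm1, where summed Tpm1 values were 40.2 and 62.9 in ESC and iPSC and 77.2 in NSC. Region calls were also found on genes under 1 FPKM, which the comparisons leave out: 720 genes in ESC (14.6%), 672 in iPSC, 298 in NSC (6.81%) and 212 in SC (5.28%).

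The calls part ESC and SC from iPSC and NSC more often than they part the pluripotent from the differentiated pair: of 970 genes called in exactly 2 cell types, 538 (55.5%, 52.3 to 58.6) split this way, 272 by pluripotency and 160 the remaining way. The tests of length, GC content and RNA level asked beforehand whether the interval of that share reached 50% in a subset, and it did in each: down to 45.6% by transcript length, where 1 of 3 groups reached it, to 43.3% by GC content, where 2 of 3 did, and 46.8% among the 131 genes within 2-fold in all 4 libraries, where the share itself was 55.7% against 31.3% and 12.98% for the other splits. That bar was lenient, since 50% is not the chance level with 3 pairings, intervals widen with fewer genes, and this split stayed the most frequent in each of the 3 groups (48.9% to 63.7%); so length and GC content may contribute without being shown to account for the whole, and RNA level is not excluded by these few genes, although the share was 58.8% (54.6 to 62.9) of 558 genes at 5 FPKM or more, a set looked at after the fact. A batch shared by ESC with SC and by iPSC with NSC is a candidate explanation. In the RNA libraries, rho with transcript length was -0.34 for ESC plus SC minus iPSC minus NSC. It was -0.18 for ESC plus NSC minus iPSC minus SC and -0.23 for the pluripotent minus the differentiated pair. The first 2 differ in size by 0.164 (0.13 to 0.20). GC content, looked at after the fact, gave 0.40 against 0.12 for them. Both of these contrasts hold the difference ESC minus iPSC, whose own rho with length was -0.44. They differ only in the sign of NSC minus SC, whose rho was 0.11. The gap therefore does not by itself show that the RNA libraries pair in this way. The labels name no batch, so a shared batch stays a hypothesis.

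The NSC library was low in neural stem cell markers and high in Myc (579 FPKM) and Klf4 (303). A split of FPKM between transcripts is argued against, since summing raised the neural stem cell list's median by a factor of 1.05 (1 to 1.22), under the 2-fold it would need. For fibroblasts in place of neural stem cells, the test asked whether their markers stood at SC levels. The NSC median was 0.0212 of that in SC, but the interval (0.000728 to 0.290) reaches above 0.1, and SC is no fibroblast reference. Members went both ways. The contractile genes Tagln (0.328 FPKM in NSC against 2166 in SC) and Acta2 (0.0110 against 1795), and Col1a1 (0.494 against 539.9), were low in NSC. Col3a1 (23.8 against 27.9) and S100a4 (13.7 against 116) were present, so the list does not decide. Neural differentiation of the culture also stays open: the neuron, astrocyte and oligodendrocyte median was 0.273 of the neural stem cell median, with an interval of 0.0616 to 16.4 over 10 genes, while Neurod1 stood at 125.

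The highest of 5 expression groups was called less often than the middle one in iPSC, NSC and SC. Ribosomal protein and oxidative phosphorylation genes do not account for this in iPSC and NSC: without them the highest group was called in 62.1% and 45.01% against 75.1% and 67.5% in the middle, and the upper bound of the highest minus the lower bound of the middle was -8.93 points or lower. Transcript length was tested among the longest of 3 length groups (3594 nt or more). There the drop stayed in iPSC and NSC, at 80.7% and 65.03% against 88.9% and 79.98%, with bounds apart by -1.73 points or lower. It was narrower than over all genes, where the shares were 59.1% and 43.2% against 75.1% and 67.4%. The group has no upper limit, so lengths can still differ within it, and length is not excluded as a contributor. In that group ESC (83.5% and 83.8%) and SC (89.4% and 86.4%) showed no drop, so length remains open for SC as well. The peak caller and its treatment of abundant transcripts are not given in the sources used here and were not tested.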

How the results depend on the processing

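The alternatives that leave out genes listed at 0, count coding transcripts alone or match random lists on transcript length or GC content were chosen after the data were seen. Of 240 alternatives to 44 results on comparisons, 143 kept the count within 1.5 times, or the value within its interval, 92 moved beyond and 5 reversed; of 1164 for named genes in RNA, 54 fell below 2-fold and 6 rose above it. Of 389 for the RNA lists (judged by whether the percentile lies outside the central 95%, not by the median) 24 lost and 16 gained that side, of 144 for the lists' m6A shares 12 lost and 3 gained it, and of 120 for named m6A genes 48 no longer kept the full difference. Shares by region moved in 49 of 100. Depth is unknown. Pseudocounts and centring for graded m6A levels were not run, since calls are yes/no. No paired analysis was possible because each group has 1 library. Unless its construction shows it, the cause was not tested.

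Genes higher in the pluripotent pair numbered 1081 with pseudocount 0.1, 281 with pseudocount 5, 264 at 4-fold, 1145 scaled and 408 without genes listed at 0, and genes higher in the differentiated pair 716 with pseudocount 5, 414 at 4-fold and 888 scaled. ESC-high and iPSC-high genes numbered 669 and 498 with pseudocount 5 and 170 and 232 at 4-fold; NSC-high genes 894 and 658 under the same settings; SC-high genes 1805 at 4-fold and 2767 scaled. Leaving out 1 cell type eases the pair rule by construction, which does not account for the spread between omissions. The counts ranged from 969 to 1252 and from 2384 to 4949 for RNA, and from 436 to 1101 and from 207 to 341 for m6A.

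At 5 FPKM or more, fewer genes gave 122 and 20 m6A calls on the pluripotent and differentiated side, 362 for iPSC alone, 598 for NSC alone, and 88 and 328 for the other pairings (ESC with NSC, ESC with SC). With no expression filter, which reads lost transcripts as lost calls, these were 662 and 296 on the 2 sides, 1506 for ESC alone, 1574 for iPSC alone, 2491 for SC alone, and 310 and 851 for the other pairings. The share called was 73.2% in ESC, 59.3% in NSC and 71.2% in SC at 5 FPKM or more; 51.5%, 51.9%, 43.4% and 50.6% in ESC, iPSC, NSC and SC with no filter; 43.7%, 44.7%, 38.5% and 40.0% with 2 or more regions; and 71.2%, 71.3%, 60.1% and 68.8% in coding transcripts. At 5 FPKM or more Spearman's rho turned to -0.00143 in ESC and -0.0247 in SC, and was -0.203 in iPSC and -0.208 in NSC; the highest of 5 expression groups minus the middle was -5.77 points in ESC and -20.9 in iPSC, and with every transcript -18.9 in NSC and -6.82 in SC.

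For expression against calls, the shift from genes called in both, at 5 FPKM or more, was 0.38 and -0.31 (ESC alone and iPSC alone), -0.30 (NSC alone against ESC), 0.44 and -0.48 (ESC and SC), 0.27 (iPSC against SC) and 0.0825 (NSC against SC). With no filter it was -0.57 (iPSC against ESC), 0.91 and -0.85 (ESC and NSC), 1.76 and -0.94 (ESC and SC), -0.43 (NSC against iPSC), 1.51 and -0.75 (iPSC and SC) and 0.76 (NSC against SC), and it turned to 0.58 for iPSC against NSC and to -0.28 for SC against NSC. With 2 or more regions it was -0.90 for SC against ESC. The contrast added later, genes called in the first alone minus those called in the second alone, was 0.86 (ESC, iPSC), 0.65 (ESC, NSC), 1.43 (ESC, SC), -0.10 (iPSC, NSC), 1.05 (iPSC, SC) and 0.18 (NSC, SC). At 5 FPKM or more it was 0.69 (ESC, iPSC), 0.42 (ESC, NSC), 0.92 (ESC, SC) and 0.57 (iPSC, SC) and turned to -0.15 (NSC, SC); with no filter 1.06 (ESC, iPSC), 1.76 (ESC, NSC), 2.70 (ESC, SC), 1.01 (iPSC, NSC), 2.26 (iPSC, SC) and 1.04 (NSC, SC); with 2 or more regions 1.69 (ESC, SC).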

Other observations

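All observations here were looked for after the lists were tabulated, and carry no explanation. Zfp genes, a large family of DNA-binding proteins, were called more often than random genes of the same expression in ESC (152 of 196, 77.6%, percentile 99.99), iPSC (186 of 228, 81.6%, percentile 100) and SC (176 of 235, 74.9%, percentile 100), and at percentile 87.4 in NSC (176 of 279, 63.1%); among genes at 5 FPKM or more the percentiles in ESC and iPSC lay inside the central 95%. Oxidative phosphorylation genes were called in 31 of 75 in ESC (41.3%), 13 of 75 in iPSC (17.3%) and 12 of 74 in SC (16.2%), each at percentile 0, but in 26 of 75 in NSC (34.7%), at percentile 42.4. The m6A enzymes and binders themselves carried calls in 17 of 20 expressed genes in ESC, 19 of 21 in iPSC, 16 of 19 in NSC and 19 of 20 in SC. Germ cell and Leydig cell markers were called in 2 of 7 in ESC and 1 of 7 in iPSC (percentile 0.275). None of these percentiles matches transcript length, so length may contribute to them.

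Prominent single genes outside the lists' main trends were the testis-type paralogs Rpl10l and Rpl39l, at 53.7 and 19.1 FPKM in ESC, 63.5 and 28.6 in iPSC, and listed at 0 in NSC and SC. Paralogs share sequence with the main gene, so their values are uncertain. Cox6b2 and Cox7a1, subunit genes of cytochrome c oxidase, stood at 135 and 166 in ESC against 19.7 and 41.1 in iPSC. Hoxb9 stood at 40.9 FPKM in SC and 0.0158 in NSC, and 0 of 26 Hox genes reached 1 FPKM in NSC.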
